A study of Homo sapiens with 4 samples.

How the data were processed

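Histone H3 acetylation was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in H929, an established human multiple myeloma cell line. Per the labels, the cells either overexpressed AIMP1 or were wild type. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 minutes, sonicated chromatin was precipitated with an antibody against acetylated histone H3, and library fragments of 100 to 300 bp were selected. The series holds 4 samples: an acetyl-H3 library and an input library for each group. The acetyl-H3 libraries came with 1 peak list each and were analysed. The inputs came with no processed file and were not analysed here.

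The submitters' processing notes name cutadapt, Trimmomatic, FastQC and Bowtie2, with no versions or roles. The peak caller, its threshold, the genome build and the use of the input libraries are not given in the sources used here. Each list comes from 1 library, so no replicates were pooled. Per the file headers, each peak has a start, an end, a fold enrichment, a p-value, a class of genomic place, a distance to a transcription start site (TSS) and 1 gene. The fold enrichment is a ratio computed by the authors over a background that the file headers do not describe. The p-value is the authors' own value per peak, and the largest in each deposited list was 0.001. The p-values are plain numbers where −log10 values had been foreseen, and were used as deposited. Fold and p-value belong to a peak within its own list, and they were used here to describe, rank or filter peaks of that list. The exceptions are the alternatives that apply 1 fold or p threshold to both lists. The read depth of the libraries is unknown. Coordinates are printed as the deposited lists give them, counted from 1. Gene identifiers were matched to the RefSeq annotation of GRCh38.p14: 8085 of 8100 identifiers of the overexpression list and 3489 of 3497 of the wild-type list matched, and 99.9% and 99.8% of these lay at the same gene in that annotation. RefSeq was used only for gene names and for which genes neighbour a peak.

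All peaks lay on chromosomes 1 to 22 and X. A peak was at a promoter if the authors' annotation put it there, which covers 3 kb around a TSS. Peaks were shared if they overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1). The overlap step was tested on 1000 wild-type peaks, of which 200 were moved onto overexpression peaks and the rest beyond the chromosome ends. It found 200 of 200 planted overlaps and 0 false ones, but false ones were not possible there. The overlap by position alone was measured with 100 circular shifts of the peaks along their chromosomes. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Genes were called by promoter peaks in both lists, in the overexpression list only, or in the wild-type list only. With 1 library per group no test across samples was possible, and no p-value is given for any difference between the groups. A gene with a promoter peak in 1 list only had no such peak listed at the authors' threshold in the other list, which does not show that acetylation was absent there. For 15 gene lists, with all 360 names matched to RefSeq, the number of members with a promoter peak in the overexpression list only was placed among 10000 random lists with as many peak-bearing genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

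The grouping, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 10 genes with the highest fold among those with a promoter peak in the overexpression list only and no wild-type peak within 1 kb, the 10 from the wild-type list by the same rule, the 5 highest in the overexpression list among genes whose promoter peaks overlapped, and AIMP1, ANP32A and GRB2. From each gene list it took up to 4 members with a promoter peak in the overexpression list only, up to 2 in the wild-type list only and up to 2 in both. The alternatives so fixed were an overlap of 50% of either peak, sharing within 1 kb, peaks at or above the median fold of both lists together (6.11), lists of equal length (4828 peaks), promoters within 1 kb or 3 kb by distance, any peak annotated to the gene, and all sequences listed. Chosen after seeing the data were peaks at p of at most 1e-05, genes called by every TSS within 1 kb of a peak, protein-coding genes as the background of the gene lists, and list members called also by a peak within 1 kb of a gene's end in RefSeq. The spacing of the fold values, from which relative coverage was estimated, was searched for in 4 ways, also after seeing the data, and all 4 are reported.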

Results

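Acetylated histone H3, a mark of active promoters and enhancers, was profiled in H929 multiple myeloma cells that overexpressed AIMP1 and in wild-type H929 cells, with 1 ChIP-seq library per group and no replicates. AIMP1 is a non-enzymatic subunit of the multi-tRNA synthetase complex. The comparison asks how the chromatin state differs when AIMP1 is overexpressed. The overexpression list held 9780 peaks that covered 18.5 Mb, with a median width of 1621 bp, a median fold enrichment of 7.34 and a median p of 8.44e-08. The wild-type list held 4828 peaks that covered 4.79 Mb, with a median width of 828.5 bp, a median fold of 4.47 and a median p of 0.000304. At p of at most 1e-05 were 6566 overexpression peaks (67.1%) and 543 wild-type peaks (11.2%). Fold and p are the authors' values for each peak, so they rank peaks within a list and give no direction between the lists.

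Peaks of the overexpression library lay mostly at promoters, and peaks of the wild-type library mostly in introns and between genes. The overexpression list had 8300 promoter peaks, 84.9% of its peaks (95% interval 84.1 to 85.6). The wild-type list had 1739, or 36.02% (34.7 to 37.4). Promoter peaks were thus 4.77 times as many in the overexpression list, while peaks outside promoters were 0.479 times as many (1480 against 3089). Of the wild-type peaks outside promoters, 1459 were intronic and 1331 distal intergenic; the overexpression list had 484 and 658. In the overexpression list 1069 peaks (10.9%, 10.3 to 11.6) overlapped a wild-type peak, and in the wild-type list 1074 peaks (22.2%, 21.1 to 23.4) overlapped an overexpression peak. Shifting the peaks along their chromosomes 100 times gave a median of 50.5 and at most 69 overlapping wild-type peaks. Of the shared wild-type peaks 91.7% were at promoters, against 20.1% of the unshared ones (754 of 3754). These shares depended on which peaks were kept: at p of at most 1e-05 the promoter share of the wild-type list was 56.2%, and the shared percentages were 3.11% and 36.3%. With lists of equal length the wild-type share was 13.1%, and with peaks at or above the median fold of both lists together the overexpression share was 0.701%.

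**Figure D1:**
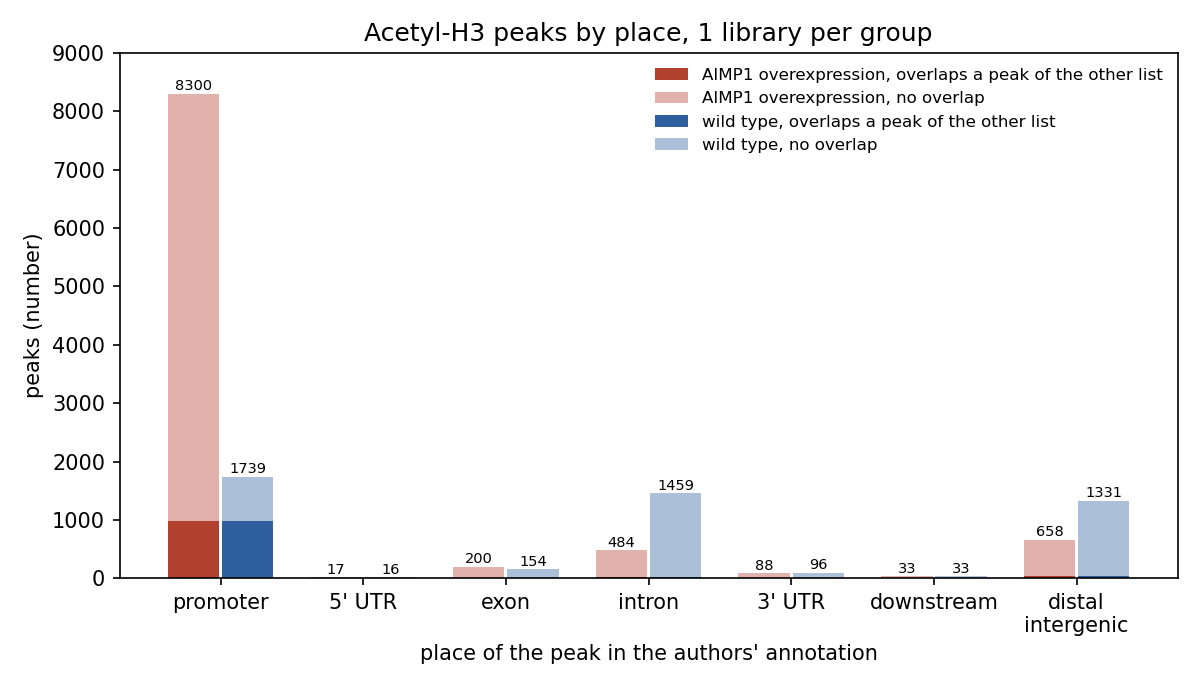
Number of acetyl-H3 peaks (vertical axis) by place in the authors' annotation (horizontal axis), for the AIMP1 overexpression library (red) and the wild-type library (blue), with dark parts for peaks that overlap a peak of the other list. Promoters hold 8300 overexpression and 1739 wild-type peaks, and introns hold 484 and 1459.

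Among genes with a promoter peak in the overexpression list only and no wild-type peak within 1 kb of it, the splicing factor gene SRSF6 had the highest fold (26.2, chromosome 20, 43456805 to 43458921, p 2.04e-33), and SRSF4 of the same family had 23.05. BANP, a nuclear protein that binds DNA, had 25.15. HNRNPH3, an RNA-binding protein, had 24.94. CDKN1B, the cyclin-dependent kinase inhibitor p27, had 24.69 in a peak 13294 bp wide (chromosome 12, 12714177 to 12727470, p 8.05e-168). The others were LOC102031319 (24.96), BRAT1 (24.1), the readthrough gene ZFP91-CNTF (23.96), the chromatin reader ZMYND11 (23.58) and CNOT3 of the CCR4-NOT deadenylase complex (23.05).

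CIITA, the master regulator of MHC class II genes, led the genes with a promoter peak in the wild-type list only, with a fold of 8.56 and a p of 4.17e-09 (chromosome 16, 10876838 to 10878069). The fatty acid elongase gene ELOVL3 followed with a fold of 6.85 and a p of 5.81e-11. POC1B and CAPS2 also had 6.85, with p of 7.69e-05 and 0.000145. SLFN12 had 6.46 and KHDC4 6.38. VPS4B, CCDC150, INHBE and BPNT1 each had 6.28. Among genes whose promoter peaks overlapped between the lists, the highest overexpression folds were at TCF3, a transcription factor of B-lymphocyte development (21.48), SPAG6 (21.44), REXO1 (19.39), the histone methyltransferase gene KMT5B (18.99) and MIR3188 (18.86). Their overlapping wild-type peaks had folds of 3.99, 3.07, 3.72, 4.35 and 3.88.

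In all, 7493 genes had a promoter peak in the overexpression list and 1632 in the wild-type list. Both lists held 1165 genes, which is 71.4% (69.1 to 73.6) of the wild-type genes. Of these genes 891 had promoter peaks that overlapped and 274 had not. The overexpression list alone held 6328 genes, and the wild-type list alone 467. Of 19974 protein-coding genes, 6769 had an overexpression promoter peak and 1478 a wild-type one; 1076 had both, where independent lists would share 501. The gene counts depended on the peaks used: lists of equal length gave 3682 genes in the overexpression list only, 928 in the wild-type list only and 704 in both, and p of at most 1e-05 gave 5578, 99 and 202, where 33 of the 99 had an overexpression promoter peak at the authors' own threshold. The wild-type-only count was also 274 when every TSS within 1 kb of a peak was counted, 1446 when any annotated peak was counted (with 2045 genes in both), and 24 at or above the median fold of both lists together (with 52 in both).

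The promoter of AIMP1 itself carried a peak in both libraries. The overexpression peak (chromosome 4, 106315281 to 106317339) had a fold of 6.94 and a p of 2.4e-07, and the overlapping wild-type peak (106316056 to 106316552) had 5.08 and 0.000582. An introduced AIMP1 gene need not carry this promoter, so the peaks do not check the labels. GRB2, the adaptor that links receptors to RAS, had no annotated peak in the overexpression list and 1 intronic wild-type peak (chromosome 17, 75346930 to 75347581, fold 4.19, p 0.000984). The authors' annotation put this wild-type peak 20592 bp from a TSS, which is not the GRB2 end described next. An overexpression promoter peak annotated to MIR3678 (chromosome 17, 75404832 to 75406496, fold 8.87, p 3.52e-07) covered an end of GRB2 in RefSeq and had no wild-type peak within 1 kb. ANP32A, an inhibitor of histone acetylation, had no annotated peak in either list. An overexpression peak annotated to SPESP1 (chromosome 15, 68816712 to 68820616, fold 18.67, p 5.02e-85) lay 278 bp from an end of ANP32A, also with no wild-type peak within 1 kb. The lists give 1 gene per peak, so a promoter shared by neighbours is counted for 1 of them. The lack of an overexpression peak annotated to GRB2 or ANP32A therefore does not show that their promoters lacked one. Counting only promoter peaks annotated to AIMP1, ANP32A and GRB2, lists of equal length left the wild-type one of AIMP1. A p of at most 1e-05 left the overexpression one of AIMP1.

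**Figure D2:**
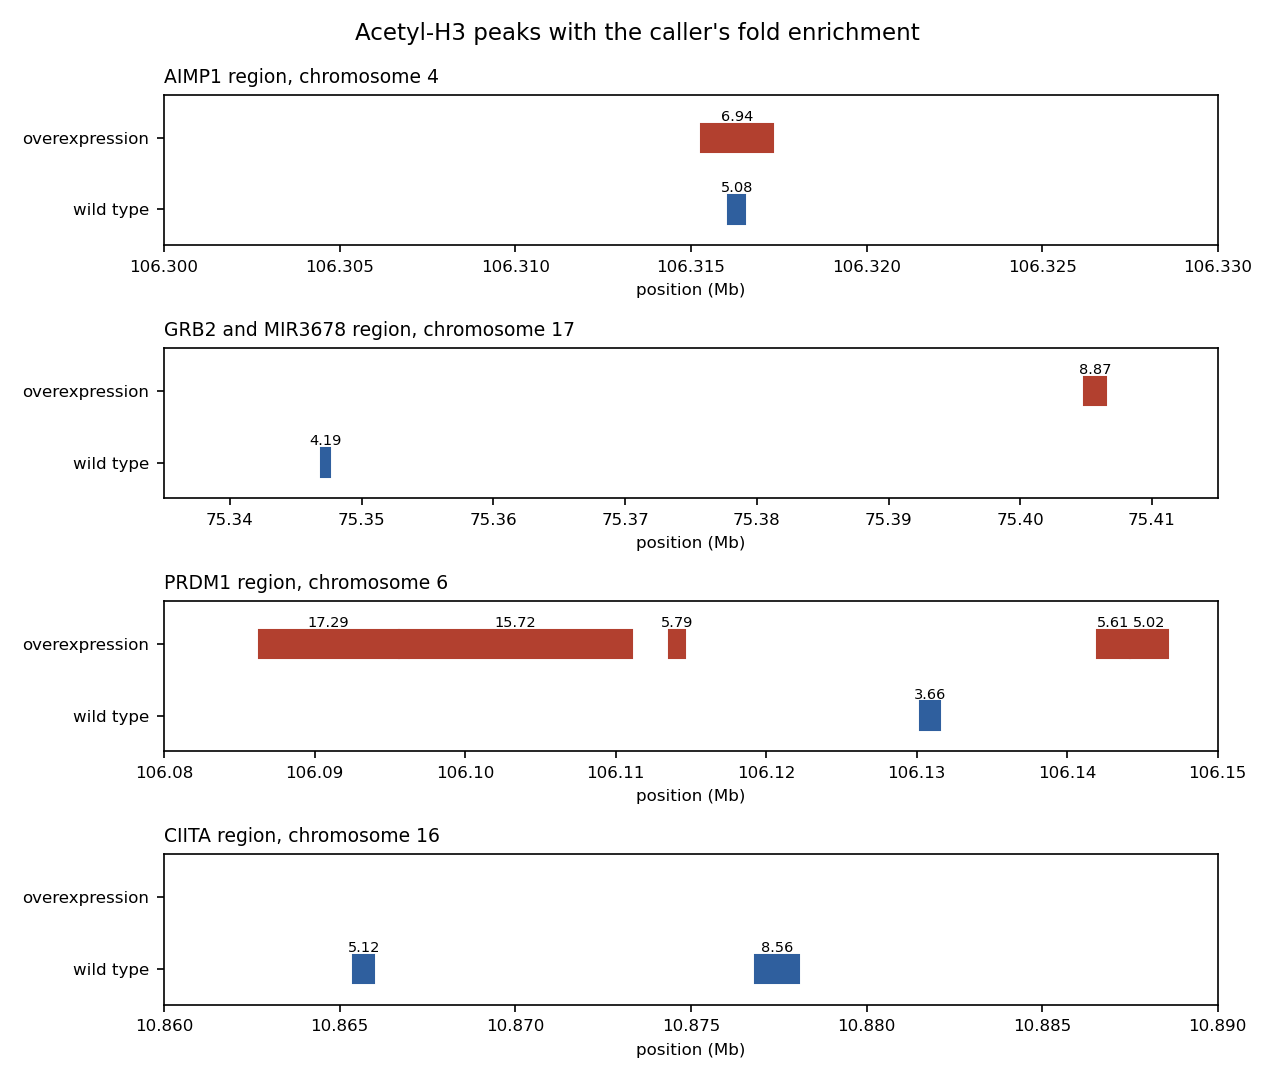
Acetyl-H3 peaks (boxes, to scale along each chromosome in Mb) of the overexpression library (red) and the wild-type library (blue) at AIMP1, at GRB2 and MIR3678, at PRDM1 and at CIITA, with the authors' fold enrichment above each box. AIMP1 has overlapping peaks of 6.94 and 5.08, and CIITA has a wild-type promoter peak of 8.56 and no overexpression peak.

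Of all 7960 genes with a promoter peak in either list, 79.5% had it in the overexpression list only, so large overexpression-only counts are not particular to a gene list. In the list of GRB2-RAS-MAPK signalling, 25 of 37 genes had a promoter peak in the overexpression list only, 6 in both and 0 in the wild-type list only. Random lists with as many peak-bearing genes had a median of 25 in the overexpression list only. With lists of equal length the 3 numbers of this gene list were 17, 2 and 4, and with any annotated peak 19, 13 and 2. The transcription factor gene EGR1 (fold 13.98), the kinase gene BRAF (13.6), the exchange factor gene SOS1 (12.9) and the feedback inhibitor gene SPRY4 (12.58) had the highest overexpression-only folds; RASA1 (9.67 in the overexpression and 4.19 in the wild-type list) and DUSP5 (9.23 and 3.3) had peaks in both. In the multi-tRNA synthetase complex, 5 of 11 genes were in the overexpression list only and 2 in both: QARS1 (8.91), RARS1 (8.38), IARS1 (7.34) and LARS1 (6.13) led the former, and EPRS1 joined AIMP1 in the latter (5.24 and 4.57). Among histone acetylation enzymes and ANP32-SET inhibitors, 21 of 34 were in the overexpression list only, 3 in the wild-type list only and 3 in both. ANP32B (15.2), BRPF1 (14.78), BRD2 (13.46) and the acetyltransferase gene CREBBP (12.58) led the first, the deacetylase genes HDAC3 (5.14) and HDAC9 (4.98) and the acetyltransferase gene KAT7 (4.12) were in the wild-type list only, and KAT5 (14.57 and 4.14) and ANP32E (11.09 and 4.79) were in both.

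Of 30 plasma cell and myeloma identity genes, 16 had a promoter peak in the overexpression list only, among them PRDM1 (fold 17.29) and XBP1 (16.51), the transcription factors of plasma cell differentiation, JCHAIN (15.87, width 10725 bp) and TXNDC5 (15.72, width 10724 bp). With any annotated peak 10 were in the overexpression list only and 11 in both, since PRDM1 and XBP1, for example, each had 1 wild-type peak outside promoters. By promoter peaks the list had 2 genes in the wild-type list only, MEF2C (4.54, p 1.02e-11) and POU2AF1 (5.53, p 0.000526), and 5 in both, with MZB1 (12.58 and 5.22) and ITGA4 (12.25 and 4.57) among them. The promoter peaks of ITGA4, BIRC2 and NFKBIA in the 2 lists did not overlap, so their folds belong to different places. Of 29 myeloma translocation and mutation genes, 14 were in the overexpression list only, with TRAF3 (16.77) and NSD2 (14.77) highest, 1 in the wild-type list only (SP140, 4.57) and 2 in both (BIRC2, 8.12 and 4.25; MAF, 7.46 and 3.59). Of 28 NF-kB pathway genes, 10 were in the overexpression list only, with BCL3 (10.84), NFKB1 (9.96) and TNFRSF1A (7.96) after TRAF3, 2 in the wild-type list only (NFKB2, 5.83; TRAF1, 4.57) and 4 in both (RELB, 9.64 and 4.52, and NFKBIA, 8.91 and 5.71, among them). Of 30 genes of the unfolded protein response and proteasome, 16 were in the overexpression list only, with ATF4 (21.48), CALR (14.16) and SYVN1 (14.03), 2 in the wild-type list only (PSMD14, 6.28; HSP90B1, 5.14) and 6 in both (PSMC1, 9.43 and 4.57, and NFE2L1, 8.17 and 5.19, among them).

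Cell cycle, ribosomal and housekeeping genes had many overexpression promoter peaks. The bone disease, B cell stage, T and NK cell, monocyte and macrophage, and erythroid and neuronal lists had few. Of 34 cell cycle genes, 19 were in the overexpression list only, with MCM7 (15.5), E2F3 (14.67) and MKI67 (14.67) after CDKN1B, 2 in the wild-type list only (MCM2, 4.57; CDK6, 3.85) and 5 in both (TOP2A, 10.37 and 3.28, and CCNA2, 8.98 and 5.03, among them). Of 37 ribosomal protein genes, 16 were in the overexpression list only, led by RPL7 (16.24), RPS19 (15.77), RPS16 (14.35) and RPS18 (11.31), 1 in the wild-type list only (RPLP0, 4.51) and 8 in both, RPL19 (14.99 and 3.35) and RPL27 (11.26 and 3.63) among them. Of 16 housekeeping genes, 8 were in the overexpression list only, led by TUBA1B (19.91), ACTB (19.39), LDHA (11.21) and EEF1A1 (9.96), and 3 in both, PPIA (16.26 and 3.02) and GAPDH (10.44 and 3.49) among them. Of 25 osteoclast and bone disease genes, 3 were in the overexpression list only (FOSL1, 9.96; CCL3, 7.87; OSCAR, 6.38) and 1, TRAF6, in both (7.22 and 4.65); with any annotated peak, 4 were in the overexpression list only and 5 in the wild-type list only. Of 17 B cell stage genes, BACH2 (7.86) and BCL6 (7.51) were in the overexpression list only, and CIITA and BLK (4.96, p 5.96e-07) in the wild-type list only. Of 17 T and NK cell genes, BCL11B (8.33) was in the overexpression list only, KLRD1 (4.37) in the wild-type list only and GATA3 (4.69 and 3.76) in both. Of 15 monocyte and macrophage genes, ITGAX (5.14) was in the wild-type list only, and of 14 erythroid and neuronal genes, SYT1 (6.29) was in the overexpression list only.

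**Figure D3:**
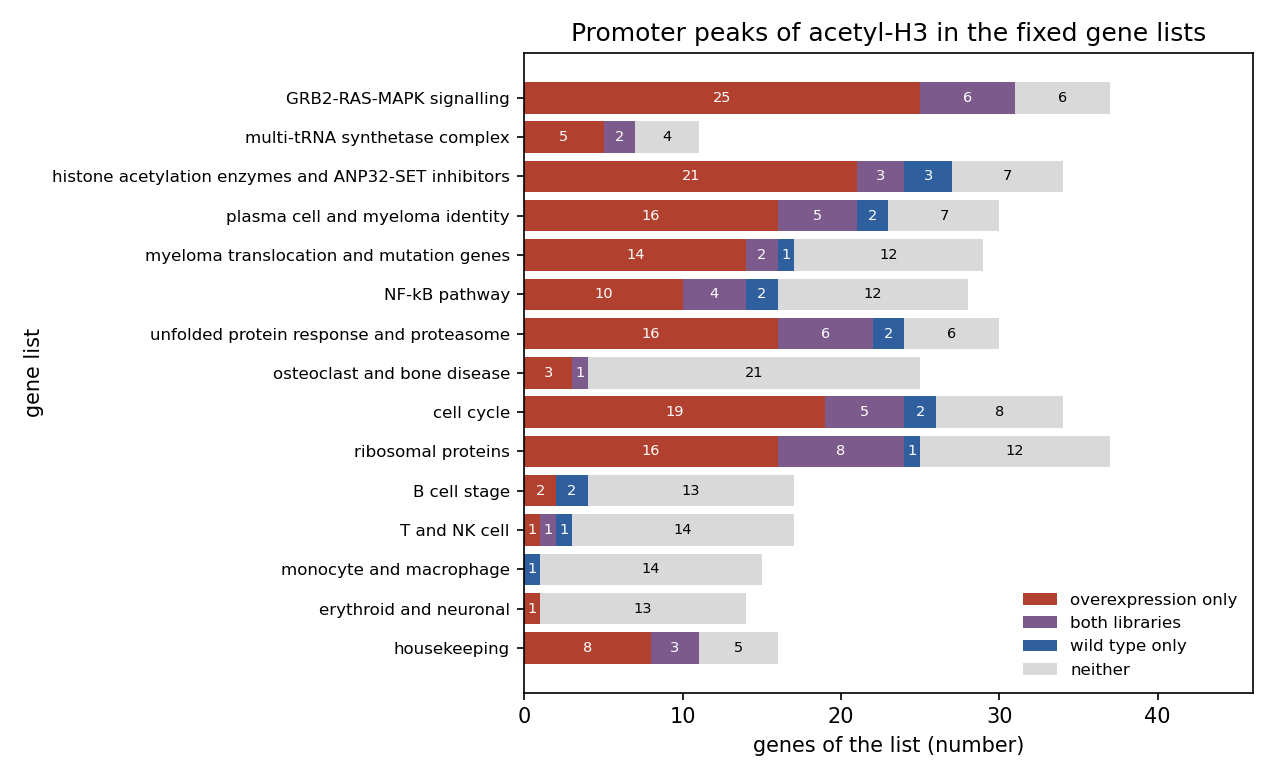
Genes of each fixed list (horizontal axis, number of genes) with an acetyl-H3 promoter peak in the overexpression library only (red), both libraries (purple), the wild-type library only (blue) or neither (grey). GRB2-RAS-MAPK signalling has 25, 6, 0 and 6 genes in these classes, and the monocyte and macrophage list has 0, 0, 1 and 14.

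Among genes with a promoter peak in either library, the percentile of a list's number of overexpression-only genes among 10000 random lists was 55.2 for GRB2-RAS-MAPK signalling, 30.2 for the multi-tRNA synthetase complex, 39.5 for acetylation enzymes and inhibitors, 12.3 for plasma cell identity, 58.9 for myeloma genes, 6.12 for NF-kB, 7.29 for the unfolded protein response and proteasome, 39.8 for bone disease, 21.1 for cell cycle, 3.64 for ribosomal proteins, 10.9 for B cell stage, 5.71 for T and NK cell, 10.2 for monocyte and macrophage, 60.2 for erythroid and neuronal and 28.6 for housekeeping genes. Against all protein-coding genes, a background chosen after seeing the data, the number of members with an overexpression promoter peak lay at percentile 100 for the GRB2-RAS-MAPK (31 genes, random median 13), acetylation, plasma cell (21, random median 10), unfolded protein response and cell cycle lists. It lay at 99.98 for ribosomal, 99.7 for housekeeping, 99.03 for myeloma, 97.545 for multi-tRNA synthetase and 95.9 for NF-kB genes, and at 2.70 for bone disease, 2.67 for T and NK cell, 2.19 for B cell, 1.29 for erythroid and neuronal and 0.13 for monocyte genes. Of all protein-coding genes, 33.9% had an overexpression promoter peak. Ribosomal and housekeeping genes also lay near the top, so a high percentile against this background is not particular to a pathway. The number with a wild-type promoter peak lay at 99.93 for ribosomal, 99.9 for unfolded protein response, 99.5 for plasma cell, 99.3 for cell cycle, 99.15 for NF-kB, 97.7 for acetylation, 96.4 for GRB2-RAS-MAPK, 93.6 for housekeeping and 88.1 for multi-tRNA synthetase genes. It lay at 76.2 for T and NK cell, 75.7 for B cell, 73.7 for myeloma, 50.2 for monocyte, 29.5 for bone disease and 17.5 for erythroid and neuronal genes. Of 166 list genes without an overexpression promoter peak, 44 had an overexpression peak within 1 kb of an end of the gene in RefSeq, PSMD14, MCM2 and RPLP0 among them. With such peaks counted, the overexpression-only genes of the B cell list were 4 and those of the monocyte list 1, and the cell cycle list had 0 wild-type-only genes, since MCM2 and CDK6 both had such a peak. With lists of equal length, overexpression-only genes were 9 for plasma cell identity, 2 for the multi-tRNA synthetase complex, 5 for housekeeping and 0 for erythroid and neuronal genes.

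Chromosome 19 had the most overexpression peaks per Mb (14.4) and also the most wild-type peaks per Mb (3.24). Chromosomes 5, 7, 11 and 13 had 2.96, 2.67, 2.44 and 2.38 wild-type peaks per Mb. On chromosomes 4, 5 and 13 wild-type peaks outnumbered overexpression peaks (301 against 295, 537 against 530 and 272 against 204), and on chromosome X there were 5 wild-type and 151 overexpression peaks.

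**Figure D4:**
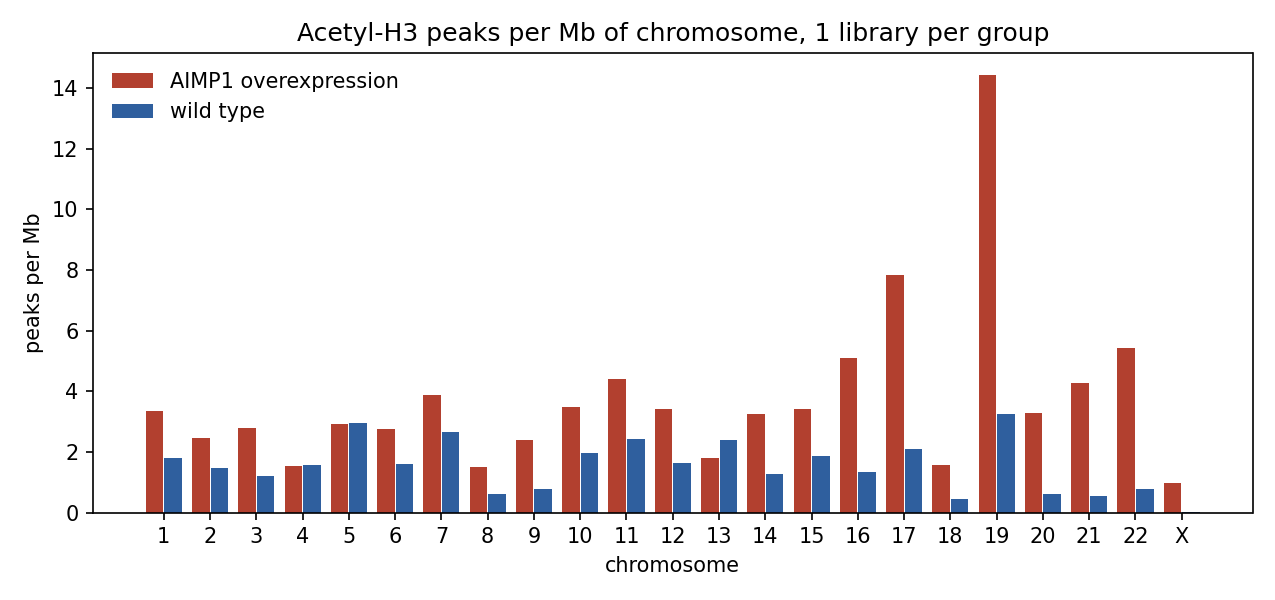
Acetyl-H3 peaks per Mb of chromosome (vertical axis) for chromosomes 1 to 22 and X (horizontal axis) in the overexpression library (red) and the wild-type library (blue). Chromosome 19 has 14.4 overexpression and 3.24 wild-type peaks per Mb, and chromosome 13 has 1.78 and 2.38.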

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

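Chosen only after the result was seen were the tests at p of at most 1e-05, those by every TSS within 1 kb, and the calls by gene ends in RefSeq. No paired analysis was possible because each group had 1 library, and its replicate number is only a name. The higher number of peaks and of promoter genes in the overexpression list, and its higher promoter share, held under the alternatives that gave both values, but several of these could not have shown otherwise. A fold or p threshold common to both lists removes mostly wild-type peaks, whose folds and p-values are weaker, and lists of equal length fix the number of peaks. With an overlap of 50% of either peak, the shared percentages were 9.27% of overexpression and 19.2% of wild-type peaks, and within 1 kb they were 12.3% and 24.5%. At or above the median fold of both lists together, 177 wild-type peaks were left, the shared percentages were 0.701% and 27.1%, the promoter shares 91.6% and 43.5%, the wild-type-only genes 24 and the genes in both 52. With lists of equal length the shared percentages were 12.7% and 13.1%, the overexpression promoter share 93.8%, the genes 3682 in the overexpression list only, 928 in the wild-type list only and 704 in both, and 1 promoter peak, the wild-type one of AIMP1, was left at AIMP1, ANP32A and GRB2. Promoters within 1 kb gave shares of 81.6% and 28.8%. Any annotated peak gave 1446 wild-type-only genes and 2045 in both, and every TSS within 1 kb gave 274 wild-type-only genes. At p of at most 1e-05 the wild-type list had 543 peaks, the shared percentages were 3.11% and 36.3%, the promoter shares 92.7% and 56.2%, the wild-type-only genes 99, the genes in both 202, and 1 promoter peak, the overexpression one of AIMP1, was left at AIMP1, ANP32A and GRB2. These alternatives keep fewer peaks or change a definition, and beyond that the cause was not tested. Of the 15 gene lists, the overexpression-only count stayed within 1.5 times for 13 with any annotated peak, 11 with lists of equal length and 13 with gene ends in RefSeq. The small wild-type-only and shared counts moved more often: they stayed within 1.5 times for 8 and 9 lists with any annotated peak, 8 and 9 with lists of equal length, and 10 and 13 with gene ends. With any annotated peak the acetylation genes in both lists were 8, those of the unfolded protein response 10 and the NF-kB genes in the wild-type list only 5; with lists of equal length the wild-type-only genes were 5 for ribosomal proteins and 5 for the cell cycle. Using all sequences listed, or promoters within 3 kb by distance, changed no value and tests nothing. Read depth is unknown, so an unlisted peak is not evidence of missing acetylation.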

Other observations

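Chosen only after the result was seen were the tests of even spread, of coverage, of neighbouring genes and of closeness to the threshold; the test over 5 Mb windows was added after the test over chromosomes had left copy number open. The widest overexpression peaks were at COMMD3-BMI1 (25.6 kb), RUNX2 (18.3 kb, with the highest fold of the list, 27.15, and a wild-type promoter peak of the same gene at another place), the ribonucleotide reductase gene RRM2 (17.1 kb), CDH9 (16.3 kb), PRDM1 (15.5 kb), ZBTB38 (15.3 kb) and the long non-coding RNA gene NEAT1 (15.3 kb). Peaks of at least 10 kb numbered 27 in the overexpression list and 1 in the wild-type list, near LOC100506474 (11.9 kb). IGLL5, in the immunoglobulin lambda region, had the lowest p of the overexpression list (3.97e-288). The genes with most overexpression peaks were HPCAL1 (11) and CUX1 (10). The wild-type list also had peaks annotated to them, 4 and 5.

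The wild-type list placed groups of peaks around a few long or non-coding genes, all outside promoters. LINC01031 on chromosome 1 had 16, LINC01950 on chromosome 5 had 14, CNTN5 on chromosome 11 and LINC01052 on chromosome 13 had 12 each, and FAT4 on chromosome 4 and MEF2C-AS1 on chromosome 5 had 10 each. The overexpression list had 0, 0, 1, 0, 1 and 3 peaks annotated to these genes. The 5 Mb window with most unshared wild-type peaks outside promoters lay at 105 to 110 Mb of chromosome 5 (41, with 0 overexpression peaks outside promoters), and the one with most overexpression peaks outside promoters at 40 to 45 Mb of chromosome 21 (43, with 0 such wild-type peaks).

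Unshared wild-type peaks outside promoters were unevenly spread over chromosomes. An even chance spread is argued against by a chi-square of 45.2 per degree of freedom. Copy number of whole chromosomes may contribute but stays open: over 23 chromosomes their density had a Spearman rho of 0.195 (bootstrap 95% interval -0.324 to 0.642, permutation p 0.365) with the median fold of overexpression promoter peaks. Over the 575 windows of 5 Mb that held such a wild-type peak or any overexpression peak, their number had a rho of 0.40 (0.328 to 0.468) with overexpression peaks outside promoters, but 0.382 with overexpression promoter peaks, so copy number of segments cannot be told apart from a general density of peaks and genes. A difference between the cultures stays open and untested.

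The overexpression list held more peaks than the wild-type list, with the surplus at promoters, and weaker enrichment of the same sites in the wild-type library stays open there: 70.5% (215 of 305, 65.0 to 75.6) of wild-type promoter peaks at p of at most 1e-05 overlapped an overexpression peak. Outside promoters the share was 10.1% (24 of 238, 6.57 to 14.6), but the overexpression list held fewer peaks there, so this value does not bear on the surplus. The spacing of the fold values cannot tell whether the wild-type library had lower coverage, for which a ratio under 0.5 was looked for. The first of 4 searches gave a wild-type over overexpression background ratio of 0.918, or 0.827 under another formula for fold. Searching a wider range of spacings changed the wild-type spacing from 0.571 to 0.190 in 2 searches and the ratio to 2.75, or 4.68. All ratios lay above 0.5, but no conclusion is drawn from them. The spacing was not determined, and the fold formula is not given in the sources used here. On the first search's spacing (within 0.006) lay 23.4% of wild-type and 43.0% of overexpression values, where chance gives 2.10% and 2.29%. The surplus was also seen in the housekeeping list, where 11 of 16 genes had an overexpression promoter peak and 3 a wild-type one. In the B cell list and in the T and NK cell list, 2 genes had an overexpression promoter peak and 2 a wild-type one. In the monocyte list the numbers were 0 and 1, in the bone disease list 4 and 1, and in the erythroid and neuronal list 1 and 0. These counts are too small to show or deny a surplus. With peaks near gene ends in RefSeq counted, the B cell list had 4 and 2, the T and NK cell list 2 and 4 and the monocyte list 1 and 1. AIMP1 overexpression, which differs with the library, cannot be told apart from library quality with 1 library per group.

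For the 467 genes with a promoter peak in the wild-type list only, annotation to a neighbour is argued against as the main source: 11.8% (57 of 485, 9.02 to 15.0) of their promoter peaks overlapped an overexpression peak. It may account for a part, since 73 of the 467 genes had an overexpression peak within 1 kb of the TSS. Among the 17 wild-type-only genes of the gene lists, 5 had one within 1 kb of an end in RefSeq. Wild-type calls close to the threshold may also contribute and stay open. Of the promoter peaks of the 467 genes, 67.6% (328 of 485, 63.3 to 71.8) had p above 1e-04. The share was 59.0% (739 of 1253) for genes in both lists. Over all wild-type promoter peaks the share was 1.30 times (1.21 to 1.41) as high in unshared as in shared ones, but this set holds other genes too, and the ratio of 2 looked for could not be reached, since at most 1.84 was possible. Of the 467 genes, 66 still had a wild-type promoter peak at p of at most 1e-05. A biological difference under AIMP1 overexpression stays open and untested.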
